A study of Mus musculus with 6 samples.

How the data were processed

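The series holds 6 mouse RNA-seq libraries, 3 labelled Sal_CP and 3 labelled CP, grouped by their titles. Per the labels' protocols, total RNA was made into libraries whose second strand was degraded before amplification, so that strand is kept, and sequenced as paired reads of 150 bases. The aligner, the quantifier and the authors' test are not given in the sources used here. The build was GRCm38, per the submitters' processing notes.

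The deposited values are FPKM, fragments scaled by transcript length and library total, computed by the authors for 36842 Ensembl genes in each library. No read counts were used here, and the smallest values did not fall on steps of whole reads, so depth is unknown and no interval that needs it is given. The authors' deposited fold (ratio) column equals the ratio of the mean FPKM of the groups, and their log2 column is its logarithm. The deposited p-value comes from a test that is not given, and the deposited q-value matched a Benjamini-Hochberg adjustment over genes not at 0 in every library, to within 0.000834. FPKM are relative to the total of each library, so a large share of mitochondrial transcripts lowers all other values. Of the annotation cells, 2230 gene ontology and 6 pathway cells are not used here. No per-sample column was left out, and no libraries held identical values.

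Values were taken as log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 6 libraries, which left 12241 genes. Groups were compared with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and robust fitting off, on 4 residual degrees of freedom and 7.76 prior ones. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Changes are Sal_CP minus CP, and ± is the SD over 3 libraries. For single values, two-sided exact permutation tests over all assignments of the libraries were used. The 33 gene lists were compared with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, where at least 5 members were tested. Members of a list were also adjusted over the list alone. Annotation terms with 10 to 500 background genes were tested by Fisher's exact test, one-sided, against 10026 tested genes that carry a term. Gene IDs matched GENCODE M21, the source of coordinates, in 99.7% of cases. Figures were drawn with matplotlib 3.10.9.

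The groups, lists, tests, naming rule and alternatives were fixed before the data were examined. The naming rule takes called genes without overlap between groups, up to 10 per direction by size of change, or the 5 of smallest p where none was called. It leaves out predicted genes and Rik symbols. It adds 12 genes of ferroptosis, NF-κB and p53 signalling whatever their test, up to 4 called or else 2 leading members of each list, called members of enriched terms, and the 5 genes of smallest p per direction. Genes that show what kind of RNA the libraries held were chosen after their values were seen.

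The test was tested on simulated data made from these libraries with 12241 genes. limma recovered 21.4% of genes changed by 1 on the log2 scale, 82.5% by 2, 94.1% by 3 and 98.6% by 4, and 4.72% of calls were false. Simulated data without changes gave a mean of 0 calls. Each gene was drawn independently, without correlation between genes or shifts of whole libraries. These rates therefore may not hold for the real data.

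Alternatives were other pseudocounts, filters, scalings and limma options, each library left out in turn, the replicate number as a block, stricter thresholds, other list tests and other term sizes. Chosen after seeing the data were the removal of mitochondrial genes and their copies with rescaling, term enrichment of the authors' calls and 3 further marker lists. So were a test of all annotated pathways and a Gpx4 fit with 4 protamine and transition protein genes as a covariate. Alternatives that need counts were not run.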

Results

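RNA was sequenced from 6 libraries that the labels describe as GC-2spd(ts), an immortalised mouse spermatocyte line, with testis as the source. In 3 libraries (CP) cells had received 2 mM cyclophosphamide, an alkylating anticancer drug that damages germ cells, for 24 h. In the other 3 (Sal_CP) they had received the same dose for 24 h together with 100 µM salidroside, a phenylethanoid glycoside from Rhodiola. Untreated cells and cells given salidroside alone are not analysed here. The table listed 36842 genes as FPKM, of which 32375 were above 0 in at least 1 library, and the number of reads behind each value is unknown. FPKM summed to between 565944 and 697070 per library. Across tested genes, log2 values correlated at r = 0.906 to 0.959 between libraries of a group and at 0.878 to 0.95 between groups. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

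The 3 most abundant nuclear transcripts by mean FPKM, Smcp, Prm2 and Odf1, were those of late spermatids and sperm. Smcp, a sperm mitochondrial sheath protein, ranged from 13200 to 33000 FPKM, Prm2, a protamine that packs sperm DNA, from 7320 to 21400 FPKM, and Odf1, an outer dense fibre protein of the tail, from 6890 to 16800 FPKM. In CP replicate 1, Gm23935 (8048 FPKM) and CT010467 (7806) lay above Prm2 (7315). Crisp1, a protein secreted by the epididymis, ranged from 1420 to 3520 FPKM. Some meiotic and cell-cycle genes were low. Sycp3, of the synaptonemal complex, lay between 1.39 and 3.75 FPKM, and Dmc1, the meiotic recombinase, between 0.0345 and 0.299. The proliferation marker Mki67 lay between 0.428 and 1.41. Other members of the spermatocyte and meiosis list were abundant, Ldhc at 156 to 424 and Pgk2 at 564 to 1350 FPKM. Its 17 tested members had a median of 5.46 FPKM. Gapdh stayed between 1.39 and 2.1 FPKM, and Gapdhs, its sperm-specific counterpart, between 691 and 2460. Actb lay between 91.2 and 173 FPKM. Mitochondrially encoded genes took 29 to 38.1% of the FPKM total in Sal_CP and 36.6 to 50.4% in CP. Predicted genes that are copies of mitochondrial genes took a further 12.7 to 16.3% in Sal_CP and 15.7 to 20.2% in CP. Nuclear FPKM and nuclear transcripts here exclude both.

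**Figure D1:**
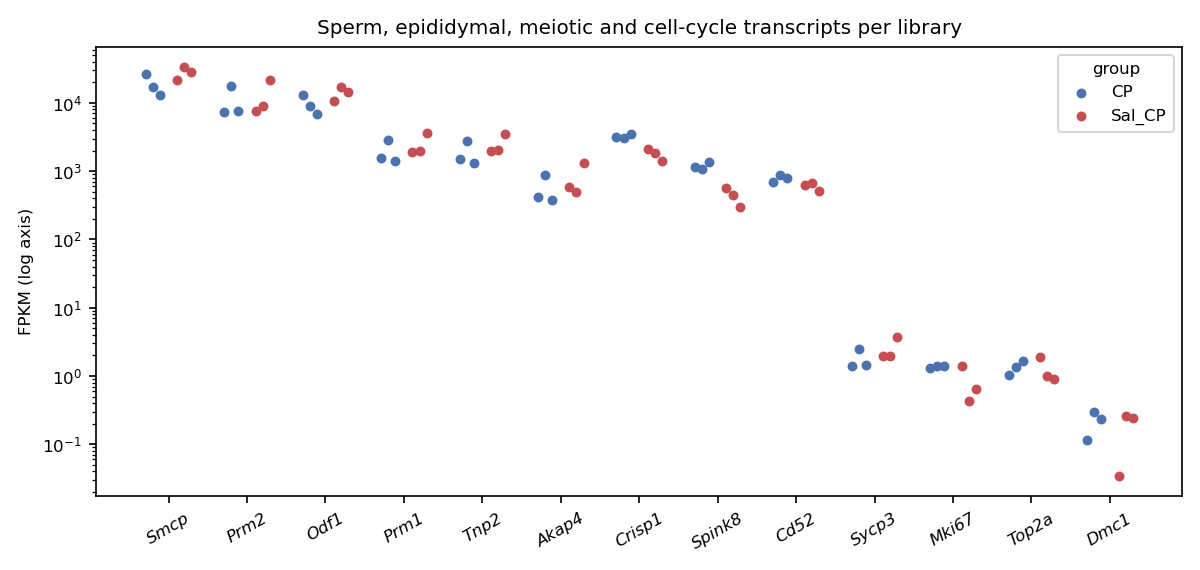
FPKM of 13 genes (log axis) in each of the 3 CP and 3 Sal_CP libraries, 1 point per library. Sperm genes such as Smcp (13200 to 33000 FPKM) and the epididymal gene Crisp1 (1420 to 3520 FPKM) lie far above Sycp3, Mki67, Top2a and Dmc1 in all 6 libraries.

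The comparison of Sal_CP with CP asks what salidroside added to cyclophosphamide, and the series names the control of GPX4 as its question. Genes past the test were all lower in Sal_CP. Akr1b7, an aldo-keto reductase, averaged 21.3 ± 5.21 FPKM in Sal_CP and 222 ± 99.6 in CP (SD, n = 3 each), and Clu, the secreted chaperone clusterin, 113 ± 34.8 against 652 ± 182 FPKM. Lcn2, the iron-sequestering lipocalin that is also an NF-κB target, averaged 3.32 ± 0.317 against 23.9 ± 8.64 FPKM, and Defb42, a beta-defensin, 1.46 ± 1.16 against 12.7 ± 4.75. The interferon-induced genes Isg15 (3.58 ± 1.54 against 20.8 ± 0.425 FPKM), Ifit3 (2.23 ± 0.571 against 12.1 ± 1.24) and Ifit3b (0.629 ± 0.455 against 4.53 ± 0.749) were lower as well. So was Sectm1a, at 0.551 ± 0.0919 against 3.78 ± 0.0607 FPKM. Epithelial markers, in lists drawn up after their values were seen, moved with these genes. Akr1b7, Defb42 and Clu belong to the epididymal list, whose mean log2(FPKM + 0.1) differed by -0.83 (SE 0.188), and by -0.52 (SE 0.20) without these 3. The list of epithelial junctions and keratins, which holds none of the called genes, differed by -0.92 (SE 0.263), and groups did not overlap in any of these scores.

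limma called 9 of the 12241 genes tested at an adjusted p below 0.05, 0 higher and 9 lower, and 1314 genes had an unadjusted p below 0.05 (485 higher, 829 lower) where chance gives 612. On the log2(FPKM + 1) scale, which understates the change of low genes, the changes were -3.24 (SE 0.39) for Akr1b7, -2.53 (0.38) for Clu, -2.52 (0.37) for Defb42, -2.46 (0.31) for Lcn2, -2.31 (0.30) for Isg15, -2.03 (0.26) for Ifit3, -1.80 (0.27) for Ifit3b and -1.63 (0.21) for Sectm1a. Adjusted p was 0.0152 for Akr1b7, Ifit3, Lcn2, Isg15 and Sectm1a, and 0.0319 for the others. All 8 had every Sal_CP library below every CP library. Groups did not overlap, in either direction, for 17.3% of all tested genes, where chance gives 10%. The remaining called gene is a predicted gene left out by the naming rule. Ifit3 and Ifit3b are close paralogs, and the division of reads between them is uncertain.

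In GRCm38 coordinates with the GENCODE M21 annotation, all 8 are protein-coding. Akr1b7 (ENSMUSG00000052131) spans 34412334 to 34423142 on chromosome 6, Clu (ENSMUSG00000022037) 65968483 to 65981547 on chromosome 14, and Defb42 (ENSMUSG00000054763) 63046991 to 63058149 on the same chromosome. Lcn2 (ENSMUSG00000026822) spans 32384633 to 32388252 on chromosome 2 and Isg15 (ENSMUSG00000035692) 156199424 to 156200818 on chromosome 4. Ifit3 (ENSMUSG00000074896, 34583531 to 34588731) and Ifit3b (ENSMUSG00000062488, 34607970 to 34613401) are neighbours on chromosome 19. Sectm1a (ENSMUSG00000025165) spans 121067407 to 121081220 on chromosome 11.

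The count of calls rested on single libraries and on the scaling, while the changes themselves stayed large. limma called 0 genes without Sal_CP replicate 1, 1 without Sal_CP replicate 2, 0 after median of ratios rescaling and 4 after quantile normalization. Over these and the other settings the log2 changes of all 8 named genes stayed below 0, from -3.61 to -2.92 for Akr1b7, -2.78 to -2.25 for Clu, -2.77 to -2.24 for Lcn2, -2.60 to -2.04 for Isg15 and -2.42 to -1.87 for Ifit3. They were -3.24 to -2.22 for Defb42, -2.93 to -1.56 for Ifit3b and -2.59 to -1.50 for Sectm1a. Akr1b7 passed at 12 of 16 settings, Lcn2, Isg15 and Ifit3 at 11, Clu at 8 and Defb42 at 7, and of 15 settings Sectm1a passed at 8 and Ifit3b at 5. No gene passed in the higher direction, where the smallest p belonged to Ggnbp1 (log2 change 1.48, SE 0.29, adjusted p 0.119), Speer4f1 (1.02, adjusted p 0.274), Rhno1 (1.15, adjusted p 0.274), Lrrc36 (1.03, adjusted p 0.277) and Ppp1r42 (0.91, adjusted p 0.288).

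**Figure D2:**
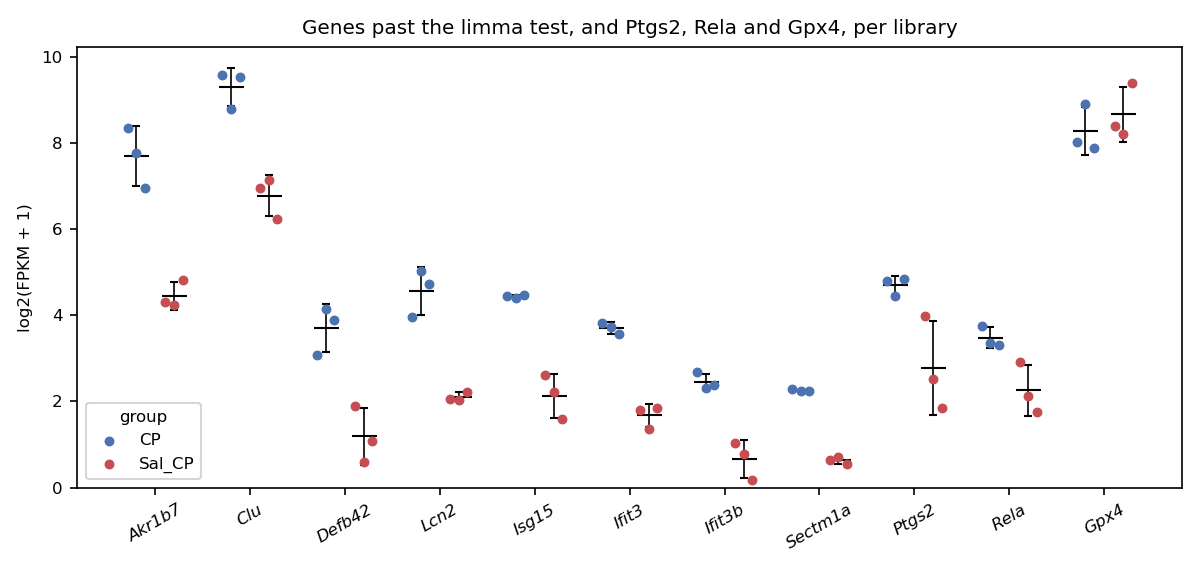
log2(FPKM + 1) of the 8 named genes past the limma test and of Ptgs2, Rela and Gpx4, 1 point per library, with the mean and SD of each group of 3. The 8 called genes show no overlap between groups, with log2 changes from -3.24 to -1.63, while Gpx4 overlaps.

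Gpx4, the enzyme that reduces phospholipid hydroperoxides and holds back ferroptosis, did not differ beyond the spread between libraries. It averaged 434 ± 207 FPKM in Sal_CP and 326 ± 134 FPKM in CP (SD, n = 3 each), with single libraries at 335.3, 294.4 and 672.2 against 260.6, 479.7 and 236.3. The log2 change was 0.39 (SE 0.42) with an adjusted p of 0.633 in limma, and the two-sided exact permutation p was 0.5, where 3 against 3 allows no p below 0.1. Gpx4 (ENSMUSG00000075706) lies on chromosome 10 from 80047166 to 80056439. Without Sal_CP replicate 3 the log2 change was 0.02. Over the 6 libraries, Gpx4 moved with the mean log2 level of Prm1, Prm2, Tnp1 and Tnp2, with Pearson's r = 0.986 (exact permutation p = 0.00278) and Spearman's rho = 0.943 (exact permutation p = 0.0167), and r = 0.891 without the 2 libraries farthest from the median. With the whole spermatid list, which holds these 4 genes, r was 0.877 (exact permutation p = 0.0194), rho 0.771 (exact permutation p = 0.103) and r without 2 libraries 0.57. These 2 relations, with adjusted p of 0.00556 and 0.0194 by exact permutation, were chosen after the values had been seen.

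**Figure D3:**
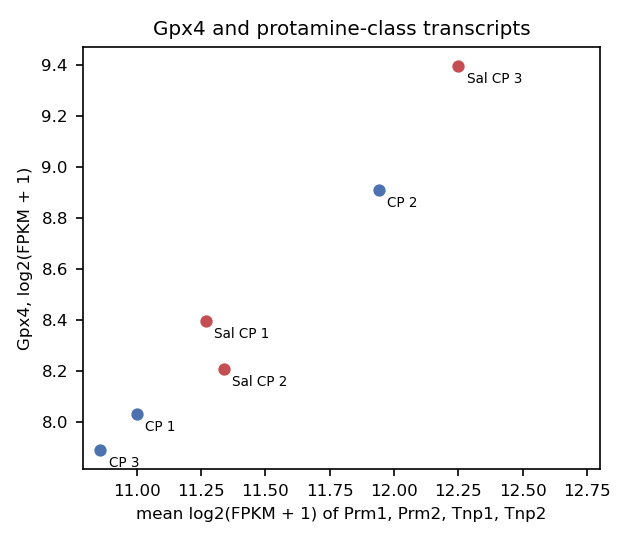
Gpx4 against the mean of Prm1, Prm2, Tnp1 and Tnp2, both as log2(FPKM + 1), 1 point per library, CP in blue and Sal_CP in red. The 6 points lie close to a line (r = 0.986), with Sal_CP 3 highest and CP 2 next.

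Other ferroptosis genes did not pass the gene test. Ptgs2, a prostaglandin synthase used as a marker of ferroptosis, averaged 7.40 ± 6.54 FPKM in Sal_CP and 25.2 ± 3.88 in CP (log2 change -1.91, adjusted p 0.213). Slc7a11, the cystine transporter, lay below the filter, at 0.6822, 0.5137 and 0.4053 FPKM in Sal_CP and 0.7016, 0.6498 and 0.9764 in CP. Adjusted p in limma was 0.577 for Acsl4 (log2 change -0.51), 0.661 for Tfrc (0.35), 0.796 for Fth1 (-0.21) and 0.917 for Hmox1 (-0.09). Tfrc, Fth1 and Hmox1 changed sign when a Sal_CP library was left out. Of the ferroptosis defence and glutathione list, 0 of 22 tested members passed, over all genes or adjusted over the list alone, and 18 lay below 0 (median -0.28, camera adjusted p 0.0436, and adjusted p = 0.819 with an estimated correlation). The list of ferroptosis promotion had 0 of 28 past the test over all genes, 3 lower adjusted over the list alone, and a median of -0.32 (camera adjusted p 0.0207, and adjusted p = 0.78 with an estimated correlation). Mboat1 (-0.93, adjusted p 0.37) and Scd2 (-0.94, adjusted p 0.455) had the smallest p in the former, and Ptgs2 and Alox15 (-1.40, adjusted p 0.322) in the latter. The mean log2(FPKM + 1) of the defence list was 3.66 in Sal_CP replicate 1, above every CP library (3.401, 3.597 and 3.351), and 2.95 and 2.85 in the other Sal_CP libraries. Without Sal_CP replicate 1, where the median of all tested genes was -0.298 (-0.123 with all libraries), the defence list's mean change of -0.30 was -0.55. Its camera call was lost without Sal_CP replicate 2 (-0.20, adjusted p 0.123), Sal_CP replicate 3 (-0.15, adjusted p 0.217) or CP replicate 2 (-0.22, adjusted p 0.147), and it passed at 9 of 16 settings, with mean changes of -0.55 to -0.14. The promotion call was lost without CP replicate 1 (mean change -0.29 against -0.36 with all libraries, adjusted p 0.0502), and its mean change was -0.58 without Sal_CP replicate 1. In the same comparison the epithelial junction and epididymal scores differed by -0.92 (SE 0.263) and -0.83 (SE 0.188), without overlap between groups.

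Interferon-response genes were lower in Sal_CP as a group. All 24 tested members of the type I interferon list had a log2 change below 0, with a median of -0.83, where the median of all tested genes was -0.12. Isg15, Ifit3 and Ifit3b fell over all genes, and 20 were lower when adjusted over the list alone. camera with the preset correlation gave an adjusted p of 1.35e-15, and adjusted p = 0.746 with an estimated correlation. The epithelial junction score was lower in the same 3 libraries (3.34, 2.90 and 2.48 in Sal_CP, 3.87, 3.66 and 3.94 in CP). NF-κB target genes were also lower, with 30 of 35 below 0 and a median of -0.55. Among them 1, Lcn2, fell over all genes and 9 were lower adjusted over the list alone (camera adjusted p 4.95e-06, and adjusted p = 0.756 with an estimated correlation). Their mean log2(FPKM + 1) was 3.23, 2.05 and 1.86 in Sal_CP and 3.30, 3.23 and 2.69 in CP, and the mean change of -0.69 was -0.43 without Sal_CP replicate 3 and -1.12 without Sal_CP replicate 1, past camera in both. Of the NF-κB pathway components 25 of 29 lay below 0 (median -0.30, camera adjusted p 0.0178, and adjusted p = 0.819 with an estimated correlation), 0 passing alone. Their mean log2(FPKM + 1) was 2.78 in Sal_CP replicate 1, above every CP library (2.58, 2.46 and 2.30), and 1.90 and 1.70 in the other Sal_CP libraries. Without Sal_CP replicate 1, where the median of all tested genes was -0.298, the components' mean change of -0.32 was -0.65. Their call was lost without Sal_CP replicate 2 (-0.20, adjusted p 0.0572), Sal_CP replicate 3 (-0.11, adjusted p 0.218) or CP replicate 1 (-0.25, adjusted p 0.0817), and passed at 12 of 16 settings, with mean changes of -0.65 to -0.11. Rela, the p65 subunit, averaged 4.07 ± 2.15 FPKM in Sal_CP and 10.3 ± 1.98 in CP (log2 change -1.22, adjusted p 0.274), and Nfkb2 had -1.04 (adjusted p 0.338). Nfkb1 had a log2 change of -0.23 (adjusted p 0.637). Nfkbia, the inhibitor IκBα, had -0.37 (adjusted p 0.733), with a mean FPKM higher in Sal_CP (26.8 ± 29.5 against 24.1 ± 4.53), and its sign turned without Sal_CP replicate 2 or 3.

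Over the 33 lists fixed before the data were examined, 32 had enough members to test, and camera with the preset correlation called 18 lower and 3 higher. With an estimated correlation 0 passed, as with the directional fry test, while the mixed fry test called 3, the interferon, Sertoli and Leydig lists. The unadjusted p with an estimated correlation was below 0.05 for 2 lists. Libraries of the groups did not overlap in mean log2(FPKM + 1) for 7 of the 18 lower lists, those of interferon, unfolded protein response, matrix, drug handling, Sertoli, Leydig and myoid genes. In 6 of the 18, Sal_CP replicate 1 lay above every CP library, which Sal_CP replicates 2 and 3 did in 0.

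Stress and secretory-pathway lists were among those called lower, with 0 members past the gene test over all genes in each and estimated-correlation adjusted p from 0.746 to 0.819. Unfolded protein response genes had a median of -0.53 (21 of 23 below 0, camera adjusted p 0.000117), with Xbp1 at -0.92 and Sec61b at -0.80. Integrated stress response genes had a median of -0.36 (19 of 23, camera adjusted p 0.00898), with Wars at -1.14 and Ddit4 at -0.89. Heat shock genes had a median of -0.35 (17 of 20, camera adjusted p 0.00952), with Hspb1 at -1.11, and 1 was lower adjusted over the list alone. p53 targets (25 of 28, median -0.35, camera adjusted p 0.00469) included Ckap2 at -0.64 and Plk3 at -0.77. The apoptosis list (22 of 24, median -0.35, camera adjusted p 0.00898) included Casp9 at -0.90 and Bax at -0.60. Trp53 itself had -0.68 (adjusted p 0.444) and Cdkn1a -0.34 (adjusted p 0.696). Drug and xenobiotic handling genes lay below 0 in all 22 tested (median -0.47, camera adjusted p 0.000117), with Abcb1b at -1.06 and Mgst1 at -0.96. Matrix and TGF-β targets had 26 of 28 below 0 (median -0.50, camera adjusted p 2.16e-05), with Timp1 at -1.71 and Lox at -1.07, and 2 were lower adjusted over the list alone. All 48 cytosolic ribosomal protein genes lay below 0 (median -0.42, camera adjusted p 1.27e-05), among them Rps27a at -1.09 and Rpl10a at -0.74. Nuclear genes of oxidative phosphorylation (44 of 49, median -0.27) and mitochondrially encoded transcripts (14 of 15, median -0.39) both had a camera adjusted p of 0.00898, with Ndufa4 at -0.74 and mt-Nd2 at -0.55. Markers of other cell types moved in the same comparison: the epithelial junction score was 3.34, 2.90 and 2.48 in Sal_CP and 3.87, 3.66 and 3.94 in CP, and the spermatid list held 17.3, 23.5 and 23.6% of nuclear FPKM in Sal_CP and 19.1, 19 and 16.1% in CP.

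In 6 of these lists Sal_CP replicates 2 and 3 lay below every CP library and replicate 1 did not. In Sal_CP replicate 1 the mean log2(FPKM + 1) was above every CP library for the integrated stress response (3.58, CP 3.35, 3.45 and 3.39), p53 targets (2.96, CP 2.81, 2.84 and 2.72), apoptosis (2.40, CP 2.30, 2.23 and 2.20) and nuclear oxidative phosphorylation (4.43, CP 4.24, 4.36 and 4.27). It lay between CP libraries for ribosomal proteins (6.574, CP 6.498, 6.702 and 6.443) and heat shock genes (4.12, CP 4.07, 4.15 and 4.08). Without Sal_CP replicate 3 the mean change was -0.20 for the integrated stress response (-0.38 with all libraries), -0.21 for p53 targets (-0.35), -0.19 for ribosomal proteins (-0.41) and -0.23 for mitochondrially encoded transcripts (-0.37), all still past camera. The apoptosis call was lost there (-0.15 against -0.34, adjusted p 0.123), as was that of nuclear oxidative phosphorylation (-0.14 against -0.27, adjusted p 0.0759). Without Sal_CP replicate 1 the changes were larger, at -0.67 for the integrated stress response, -0.61 for p53 targets, -0.62 for ribosomal proteins, -0.59 for apoptosis, -0.47 for nuclear oxidative phosphorylation and -0.56 for heat shock genes (-0.36 with all libraries). The median change of all tested genes moved as well, from -0.123 with all libraries to -0.298 there and -0.0389 without Sal_CP replicate 3. Part of these shifts is therefore shared by genes outside the lists. The p53 change was -0.22 without Sal_CP replicate 2, and that of matrix genes -0.35 without CP replicate 1 (-0.57 with all libraries), both still past camera. The call of mitochondrially encoded transcripts was lost without Sal_CP replicate 1, where the mean change was as large (-0.39, adjusted p 0.378), and without CP replicate 3 (-0.19, adjusted p 0.423).

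**Figure D4:**
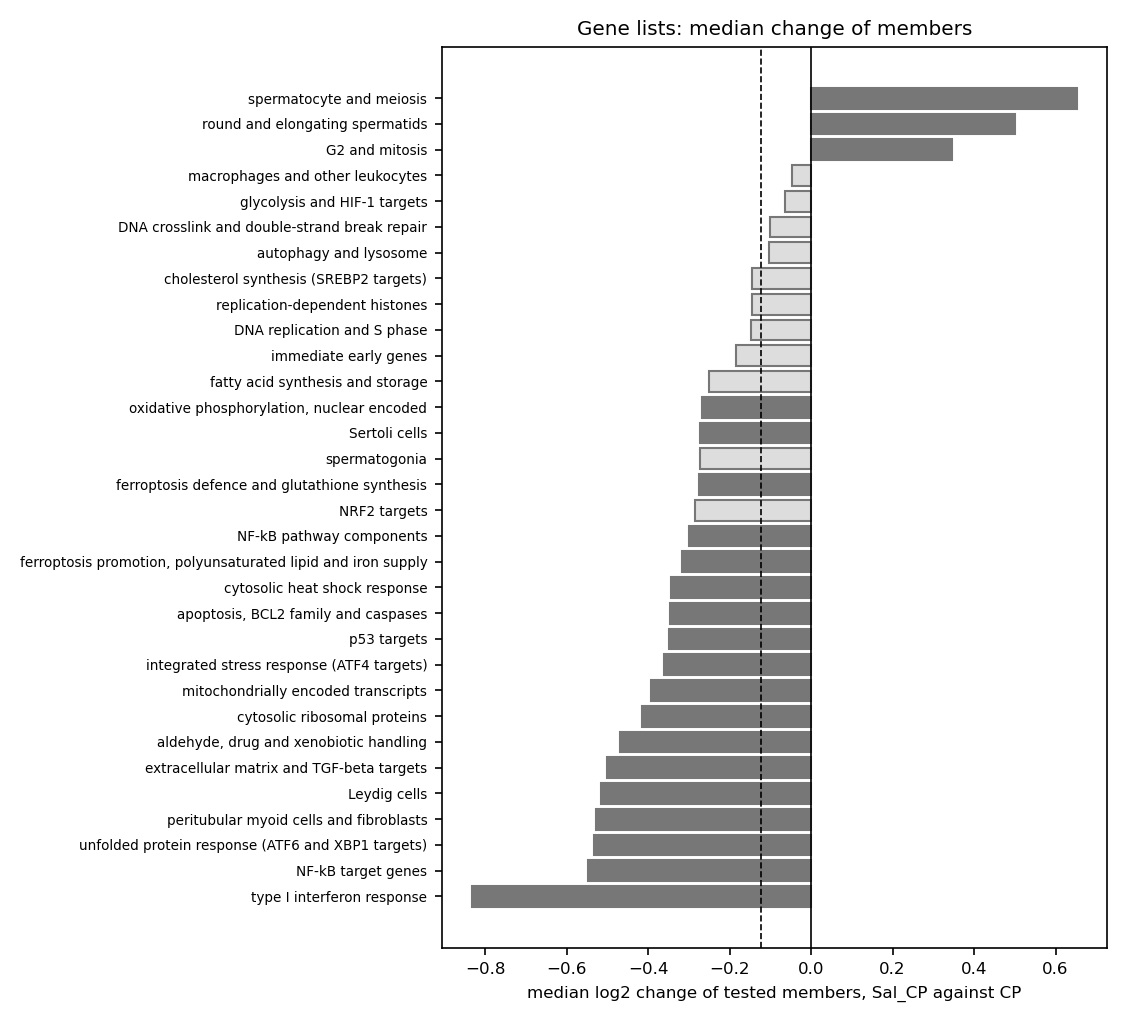
Median log2 change of the tested members of each of the 32 lists, Sal_CP against CP, with the dashed line at the median of all tested genes (-0.12). Dark bars passed camera with the preset correlation (18 lower, 3 higher), light bars did not, and 0 passed with an estimated correlation.

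Lists of spermatid, meiosis and mitosis genes were called higher. All 20 spermatid genes had a log2 change above 0 (median 0.50, camera adjusted p 3.75e-07, and adjusted p = 0.746 with an estimated correlation), with Acr at 0.83 and Izumo1 at 0.61. Of the spermatocyte and meiosis list 16 of 17 lay above 0 (median 0.65, camera adjusted p 3.75e-07, and adjusted p = 0.697 with an estimated correlation), with Tex101 at 0.76 and Smc1b at 0.69. The list of G2 and mitosis, with 13 of 16 above 0 (median 0.34, camera adjusted p 0.00407, and adjusted p = 0.746 with an estimated correlation), included Nek2 at 0.67 and Aurka at 0.73. 0 members passed the gene test over all genes or adjusted over the list alone in these 3 lists. Spermatogonia genes lay below 0 in 4 of 5 tested (median -0.27, camera adjusted p 0.127). Of the 36 mitosis members only 16 were tested. Mki67 and Top2a, both on that list, averaged lower in Sal_CP (0.826 against 1.36 and 1.268 against 1.357 FPKM). DNA replication genes lay below 0 in 13 of 21 tested. The mitosis call was lost without CP replicate 1 (mean change 0.13 against 0.26 with all libraries, adjusted p 0.0537), and the mean log2(FPKM + 1) of the spermatid list was 7.05 in Sal_CP replicate 1, below 7.15 in CP replicate 2. Without Sal_CP replicate 3 the mean change of the spermatid list was 0.29, against 0.52 with all libraries, and still past camera. The share of nuclear FPKM in the spermatid list was 17.3, 23.5 and 23.6% in Sal_CP and 19.1, 19 and 16.1% in CP. That of the epididymal list, drawn up after values were seen, was 1.69, 1.49 and 0.956% in Sal_CP and 2.66, 2.5 and 3.9% in CP.

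Somatic marker lists of the testis were lower. Leydig cell genes lay below 0 in all 7 tested (median -0.52, camera adjusted p 0.00936, and adjusted p = 0.697 with an estimated correlation), with Insl3 at -1.41, and 1 was lower adjusted over the list alone. Only these 7 of 15 members were tested, at a low median of 1.32 FPKM. Insl3 lay at 0, 0 and 0.922 FPKM in Sal_CP and 2.03, 3.18 and 1.85 in CP. Myoid and fibroblast genes lay below 0 in all 10 (median -0.53, camera adjusted p 0.00898, and adjusted p = 0.746 with an estimated correlation), with Col1a2 at -1.01. Sertoli genes had 7 of 8 below 0 (median -0.27, camera adjusted p 0.0377, and adjusted p = 0.746 with an estimated correlation), and Clu, the called member, is also made by many other epithelia. Clu (log2 change -2.53) was the only member with an unadjusted limma p below 0.05, and the only one without overlap between groups. The mean change of -0.55 thus leaned on Clu, and the list was not tested without it. Of the 20 Sertoli members only those 8 were tested, at a median of 3.14 FPKM. Without Sal_CP replicate 1 all 3 calls were lost (adjusted p 0.11 for Leydig, 0.36 for myoid and 0.169 for Sertoli genes), although the mean changes were larger, at -0.60, -0.61 and -0.76 against -0.53, -0.56 and -0.55 with all libraries. So was the myoid call without CP replicate 1 (-0.33, adjusted p 0.0638), and the Sertoli call without Sal_CP replicate 2 (-0.36, adjusted p 0.163) or CP replicate 3 (-0.49, adjusted p 0.145). The median of all tested genes was -0.298 without Sal_CP replicate 1, against -0.123 with all libraries. Other markers moved in the same comparison: the epithelial junction score differed by -0.92 (SE 0.263), and all 20 spermatid genes lay above 0.

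The other 11 lists did not pass camera: NRF2 targets (adjusted p 0.123), spermatogonia (0.127), fatty acid synthesis (0.304), cholesterol synthesis (0.543), DNA replication (0.543), crosslink and double-strand break repair (0.603), glycolysis (0.65), replication-dependent histones (0.65), macrophages and other leukocytes (0.689), immediate early genes (0.751) and autophagy (0.791). For glycolysis and for leukocytes the median was below 0 (-0.06 and -0.05) while camera, which compares a list with all other genes, gave the higher direction. The endothelial list had 1 tested member and was not tested.

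Among annotation terms, 3 of 1860 were enriched in the called genes, all in the lower direction: defense response to bacterium (3 of 8 called genes, Defb42, Isg15 and Lcn2, adjusted p 0.0185 by Fisher's exact test), defense response to virus (Ifit3, Ifit3b and Isg15, adjusted p 0.0185) and response to bacterium (Ifit3, Isg15 and Lcn2, adjusted p 0.0185). Genes are not independent replicates, and 3 genes carry each term.

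The authors' deposited table marked 196 genes as significant, 60 higher and 136 lower, against 9 in limma, and all 9 were among them. Of the 196 in the authors' deposited table, 15 were above 0 in only 1 library, and 25 of the higher genes were listed at 0 in all CP libraries and 14 of the lower genes in all Sal_CP libraries. With a mean FPKM of at least 1, 20 higher and 96 lower remained in the authors' deposited table. For Gpx4 the authors' deposited table gave a fold of 1.33 and a q of 0.642, and for Ptgs2 a q of 0.03. Across the 12241 tested genes, 97.1% had the same sign of change in both.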

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

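Called genes numbered 9 in the analysis as reported, 0 to 13 when a library was left out, 0 without a filter on low values, 0 after median of ratios rescaling, 4 after quantile normalization and 0 at an adjusted p below 0.01. With mitochondrial genes and their copies left out, chosen after seeing the data, limma called 18, all lower and including the 9. Counts at other settings were 6 to 13, and the cause was not tested. The changes of the 8 named genes stayed below 0 at every setting, lost calls included, at -3.61 to -2.92 for Akr1b7 and -1.56 or lower for all but Sectm1a (-2.59 to -1.50). They passed at 12 of 16 settings (Akr1b7), 11 of 16 (Lcn2, Isg15, Ifit3), 8 of 16 (Clu), 7 of 16 (Defb42), 8 of 15 (Sectm1a) and 5 of 15 (Ifit3b). Without Sal_CP replicate 1, 0 were called, although 4531 genes had an unadjusted p below 0.05. Without Sal_CP replicate 2, 1 was called, in the higher direction. The replicate number as a block gave 280 calls, 80 higher and 200 lower. Same-numbered libraries' deviations correlated at 0.196, -0.115 and -0.0644 and not each best with its own number, so the number is not taken to pair them. The authors' table has 196 calls. The Gpx4 change kept its sign and stayed short of the threshold at every setting run, at 0.02 to 0.70 when a library was left out, 0.39 with the replicate block, 0.59 after median of ratios rescaling and 0.17 without mitochondrial genes. The median change of all tested genes was -0.12 as scaled by the authors, 0.01 after median of ratios rescaling and -0.28 without mitochondrial genes. With a library left out it ran from -0.298 (Sal_CP replicate 1) to -0.0389 (Sal_CP replicate 3). Lists past camera numbered 21, 17 to 20 when a library was left out, 21 with the replicate block, 13 at a mean of at least 5 FPKM, where 24 lists could be tested, 0 with an estimated correlation, 0 by directional fry and 3 by mixed fry. Some lists share members, and with those left out 17 of 31 lists passed. Of the 21, 10 passed at every scaling, filter, limma option and left-out library that could test them: interferon, NF-κB target, unfolded protein, integrated stress, heat shock, matrix, drug handling, ribosomal, spermatid and spermatocyte. The other 11 kept their direction but passed only at 9 of 16 settings (ferroptosis defence), 9 of 15 (Sertoli), 12 of 16 (NF-κB components), 12 of 15 (mitochondrially encoded), 14 of 16 (ferroptosis promotion, oxidative phosphorylation, apoptosis, myoid), 14 of 15 (mitosis, Leydig) and 15 of 16 (p53). Enriched terms numbered 3, 4 and 3 at the planned settings and 21 from the authors' calls, chosen after seeing the data. Signs turned when a library was left out for Hmox1 (log2 change -0.71 to 0.23, and 0.0875 after median of ratios rescaling), Nfkbia (-1.21 to 0.0894), Tfrc (-0.27 to 0.68) and Fth1 (-0.69 to 0.0794), none of which passed. The direction against other genes also turned for lists that had not passed, with mean changes of -0.21 to 0.0769 for glycolysis, -0.32 to 0.0591 for autophagy, -0.65 to 0.14 for immediate early genes, -0.30 to -0.0404 for histones and -0.58 to 0.34 for leukocytes. The cause was not tested. Alternatives that need counts were not run, and unknown depth leaves the precision of low FPKM open.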

Other observations

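The tests in this part were chosen after the values they use had been seen, except the count of splits.

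Epithelial and secretory genes were lower in Sal_CP beyond the lists fixed in advance. In 3 marker lists drawn up once the values of several members were known, which are therefore no independent evidence, 22 of 24 epithelial junction and keratin genes lay below 0 (median -0.77, camera adjusted p 1.86e-11, and adjusted p = 0.105 with an estimated correlation). All 18 tested acute-phase and antimicrobial genes did (median -1.46, camera adjusted p 6.97e-15, and adjusted p = 0.0334 with an estimated correlation), and 19 of 24 epididymal genes (median -0.54, camera adjusted p 1.87e-06, and adjusted p = 0.105 with an estimated correlation). Called members numbered 3 in the epididymal list, 1 in the acute-phase list and 0 in the epithelial list. The epididymal list took 1.69, 1.49 and 0.956% of nuclear FPKM in Sal_CP and 2.66, 2.5 and 3.9% in CP. Spink8, an epididymal protease inhibitor, averaged 436.5 ± 137 FPKM in Sal_CP and 1195 ± 149 in CP (SD, n = 3). Of 291 annotated pathways, camera with the preset correlation called 86 lower and 0 higher, led by complement and coagulation cascades (mean change -0.62, adjusted p 7.03e-05), and 0 passed with an estimated correlation. Annotated ferroptosis (mean change -0.21, camera adjusted p 0.268), apoptosis (-0.19, 0.0917) and cell cycle (-0.16, 0.242) did not pass, unlike the fixed lists of those themes. The p53 (camera adjusted p 0.011) and NF-κB (0.0231) pathways were called lower.

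Interferon genes were lower in Sal_CP, by 1.39 in mean log2(FPKM + 0.1). As a pooled list, leukocyte markers did not fall as far: the interferon score minus the leukocyte score differed by -1.32 (SE 0.294) with no overlap between groups. This argues against an even loss of leukocytes as the only cause, but a loss of particular leukocyte types was not tested. Cd163 and S100a9, outside that list, were among the authors' lower genes. The leukocyte score was 4.82, 3.33 and 2.78 in Sal_CP and 4.1, 3.76 and 3.3 in CP. Its level in Sal_CP thus rested on replicate 1, without which the leukocyte list had a mean change of -0.58 in log2(FPKM + 1). Mitochondrial shares ran higher in CP (36.6 to 50.4%) than in Sal_CP (29 to 38.1%), which lowers other genes in CP. Unequal shares would thus hide a fall in Sal_CP rather than make one. Rescaling was bound to enlarge the fall and is no test: the mean change in log2(FPKM + 1) was -1.13 (SE 0.263) after it and -0.985 before. A smaller share of epithelial cells may account for part of it, since the interferon score minus the epithelial score differed by -0.474 (SE 0.189) with overlapping groups, so this and an effect of salidroside cannot be told apart. The real grouping gave 9 called genes and the highest other split 3, with 1 of 10 splits reaching 9, and 10 splits are too few for a share under 0.05.

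Transcripts of sperm and epididymis were abundant in libraries labelled as a spermatocyte line. In every library 11 of the 20 spermatid genes and 6 epididymal genes (Crisp1, Defb2, Spink8, Wfdc10, Wfdc15b and Cd52) reached 100 FPKM, and the epididymal list was drawn up once the values were known. A candidate explanation is RNA from sperm with epididymal tissue, since 11 spermatid genes of a list fixed beforehand and the 6 epididymal genes were abundant. Per library, the leukocyte list had a median of 5.27 to 21.1 FPKM. Medians were 0.657 to 1.22 for the mitosis list and 0.707 to 1.4 for the replication list. The spermatid list had a median of 165 to 429 FPKM. With replication and mitosis lists this low beside sperm, epididymal and leukocyte transcripts in all 6 libraries, these levels argue against a dividing spermatocyte line as the only source. No reference profile of the line was used, so how much RNA the line gave is unknown. Mislabelled libraries, a mixed sample and tissue as the source were not separated.

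The mean of Gpx4 was higher in Sal_CP without passing the test. Gpx4 followed Prm1, Prm2, Tnp1 and Tnp2 across the 6 libraries (r = 0.986) and the spermatid list (r = 0.877). Of tested genes outside that list, 0.884% correlated as highly with those 4 and 5.9% with the list, and the latter r was 0.57 without 2 libraries. A candidate explanation is that Gpx4 levels here track late spermatid RNA in each library, and an effect of salidroside on Gpx4 stays open. A limma fit with those 4 genes as a covariate (change 0.02, SE 0.20) decides nothing, since they were chosen once the values had been seen.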
